A study of Homo sapiens with 8 samples.

How the data were processed

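Polyadenylated RNA of JSL1 cells was sequenced by the authors from TruSeq stranded libraries, per the labels' protocols. The 8 libraries fall into 4 groups of 2 by the titles in the labels: unstimulated control, unstimulated CELF2-depleted, PMA-treated control and PMA-treated CELF2-depleted cells. PMA was given at 20 ng/mL for 48 hours, and depletion came from stably integrated, doxycycline-inducible hairpins, per the labels' protocols. The time and dose of doxycycline, whether control cells received it or carried a control hairpin, and whether the 2 libraries of a group came from separate cultures, are not given in the sources used here.

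The authors deposited 2 tables of splicing changes, 1 for each state, each comparing control with depleted cells. The submitters' processing notes name STAR 2.5.1b and hg19 without saying what each was used for. The column names and the Voila link in the file headers are those of VOILA, the output program of MAJIQ, whose version, annotation and read filters are not given in the sources used here. Each line is 1 LSV, and per the file headers gives, for each junction, the expected share in control and in depleted cells, the expected change between them and the posterior probability that the change is at least 20 percentage points. Shares ran from 0.025 to 0.975 and, within an LSV, summed to between 1.00 and 1.05 from the 5th to the 95th percentile. In each of the 17420 junctions without PMA and 23475 with PMA whose shares differed by over 0.1, the sign of the change was that of depleted minus control. The expected change is shrunken by the authors' model, so it can be far smaller than the difference of the 2 shares where an LSV was not called. In FAM192A with PMA, for example, shares of 43.9% and 32.1% had an expected change of -1.47 points. The posterior probability is not a p-value and is not adjusted for the number of LSVs.

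How the files were made limits what the values can say. The authors combined both libraries of a group into 1 value, so neither the spread between libraries nor the number of reads behind an LSV is known, and no standard deviation, interval or fit per library was possible. The posterior probability is the authors' own measure of error. The 2 tables were quantified separately, so differences between states were not tested for single exons. The tables hold no expression values. No column of per-sample values was left unused (0 such columns).

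An LSV was called at a posterior probability of at least 0.95 in any of its junctions, and a gene where it had a called LSV. A cassette exon was an exon-skipping LSV of 2 junctions without alternative splice sites or a retained intron, and its inclusion was the share of the shorter junction. Where an exon had both a source LSV (junctions leaving the upstream exon) and a target LSV (junctions entering the downstream exon) with the same skipping junction, both were averaged. Their disagreement served as a measure of technical spread, with a Pearson r across all such exons of 0.790 without and 0.831 with PMA. The skipping junction is shared by both, so this spread leaves out part of the error. For depletion effects it was taken on the authors' shrunken changes, which can also lower it. Exon lengths came from the exon bounds in the tables. In exons with both junctions read, 478 of 4019 bounds (11.9%) without PMA and 479 of 3995 (12.0%) with PMA differed from the length between the junctions. Exons listed with 11 nucleotides had 1 junction read and an unknown far end, and were left out in an alternative. LSVs under 2 overlapping gene IDs with the same junctions numbered 578 and 583 and were kept. Reads shared with paralogs and pseudogenes could not be resolved.

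The direction of called cassette exons was tested with a two-sided exact binomial test. Event types, the overlap of called genes, gene lists and exon frame were tested with two-sided Fisher's exact tests, and gene lists also with an exact Cochran-Mantel-Haenszel test stratified by the number of LSVs per gene, with 30 or more LSVs in 1 stratum. Event types were adjusted by Benjamini-Hochberg over 10 tests and gene lists over 32 combinations of list and state, each test separately, and results were read at a level of 0.05. Exon lengths and correlations across exons were tested with 100000 permutations, and with 10000 in the alternatives. Correlations were Pearson's and, by rank, Spearman's, used 1 exon per gene and formed a family of 3, all with p = 1e-05, so that adjustment leaves them at 1e-05. The 2 tables share no library. The effect of PMA was the difference of a group's inclusion between the tables, and main effects were means over both kinds of cells or both states. The depletion effect was the authors' shrunken change where the 2 states were compared. In main effects and their pairs it was the difference of group inclusions.

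The tests, the 16 gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule took, 1 exon or LSV per gene, the 8 largest rises and 8 largest falls of called cassette exons and the 8 largest changes of other LSVs per state, the 10 exons called in both states with the largest smaller change, the 6 with the largest difference between states, the 8 with the largest mean effect of PMA, up to 4 called members of each list, and any member of the list of reported events. A few genes that met the rule are not reported here. Alternatives were posterior probabilities of 0.90 and 0.99, calls by a change of 20 or 10 points, leaving out LSVs with a de novo junction, 2-junction LSVs alone, source or target LSVs alone, exons with both, exons with mean inclusion of 10% to 90%, all exons of a gene, and genes listed in both tables. Added after seeing the data were 1 LSV per set of overlapping genes, a background of variable LSVs, lengths from junctions, and leaving out exons listed with 11 nucleotides. Motif searches near exons were planned for a genome of the same build and were not run, since no hg19 sequence was used here.

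The code was tested on simulated data with the tables' own LSVs. Planted changes of 28 points were called in 100% of exons in both states, changes of 24 points in 78.0% of 100 exons without PMA and 65.0% of 100 with PMA, and changes of 12 points in 0%. No unplanted exon was called (0 in each of the simulations), with 20264 exons without PMA and 20153 with PMA. The simulated noise was small and known to the simulated posterior, which fixed this 0 in advance, and changes were planted only in exons of intermediate inclusion. The simulation therefore checked the code and does not measure how often real changes were missed or falsely called. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.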

Results

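Splicing was measured by strand-specific sequencing of polyadenylated RNA from JSL1 cells, a monoclonal line derived from Jurkat, a human T lymphocyte line. Cells were left unstimulated or treated for 48 hours with 20 ng/mL of PMA, a phorbol ester that activates protein kinase C. In both states control cells were compared with cells carrying stably integrated, doxycycline-inducible short hairpin RNAs against CELF2, an RNA-binding protein that regulates splicing. Whether control cells received doxycycline or carried a control hairpin is not given in the sources used here, so what either adds to the differences between control and depleted cells is unknown. The 4 groups had 2 libraries each, 8 in all. The study's title states its aim, the identification of functional CELF2 targets across the transcriptome of T cells.

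The unit of the authors' deposited tables is the local splicing variation (LSV), a set of junctions that all leave or all enter the same exon, and the value of a junction is its share of the LSV. The table of unstimulated cells listed 91480 LSVs in 10965 genes and that of PMA-treated cells 91729 LSVs in 11039 genes, with 87517 LSVs in both. An LSV was called where the authors' posterior probability of a change of at least 20 percentage points in any junction reached 0.95. Every junction share given as a percentage is the authors' value for a group, with both libraries pooled. The inclusion of a cassette exon is such a value, or the mean where both its source and target LSVs were listed. Because of the pooling, the spread between the 2 libraries of a group and the read depth are unknown. The p-values given here compare counts of genes, exons, introns or LSVs, or values across exons, not libraries. Positions are on hg19, the build named in the submitters' processing notes.

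CELF2, the target of the hairpins, was examined first. Its RNA level could not be checked, since the tables hold junction shares and no expression values. In unstimulated cells 0 of its 11 LSVs were called, with a highest posterior probability of 1.38e-05 in the authors' deposited table, and in PMA-treated cells 3 of 16 were called. With PMA, the CELF2 junction between positions 11371060 and 11372419 of chromosome 10 rose from 24.5% in control to 92.1% in depleted cells in the authors' deposited table. Without PMA its share was 91.0% in control and 92.9% in depleted cells. In the same LSV, the retained intron at positions 11371253 to 11371331 fell from 68.1% to 6.7% with PMA, against 7.7% and 5.9% without. A CELF2 cassette exon at positions 11308561 to 11308640 rose from 53.9% to 89.3% with PMA, and stood at 91.7% and 97.3% without PMA.

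The first comparison asked which splicing events respond to CELF2 depletion in unstimulated cells. The exon of ARHGEF11 at positions 156933484 to 156933558 of chromosome 1, fell from 96.3% inclusion in control to 2.9% in depleted cells, the largest cassette change in the authors' deposited table of this state. Inclusion rose from 24.6% to 94.1% in MFSD8, a lysosomal membrane protein. Among other LSVs the largest change was in RXRA, the retinoid X receptor, where 1 junction rose from 8.3% to 96.5%. In all, 901 LSVs (0.985%) in 680 genes (6.20%) were called.

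Of 20264 cassette exons measured without PMA, 127 were called, 69 with higher and 58 with lower inclusion in depleted cells (54.3% higher, two-sided exact binomial test, p = 0.375). Among the largest rises in the authors' deposited table were the receptor tyrosine phosphatases PTPRM, from 3.2% to 79.7%, and PTPRU, from 2.5% to 58.2%. Rises were also called in DZIP1, which acts in cilium formation, from 2.7% to 63.2%, in NADSYN1, an NAD synthetase, from 14.2% to 67.7%, and in PSD, an exchange factor for ARF6, from 8.7% to 69.3%. The pseudogene ANKRD20A5P rose from 23.4% to 85.0%, a value that reads shared with its paralogs leave uncertain. Among the largest falls were MED12, a subunit of the Mediator complex, whose exon at positions 70345513 to 70345563 of chromosome X went from 90.8% to 46.5%, and FAM192A, from 51.4% to 6.0%. KLHL42 fell from 47.0% to 6.2%, the zinc transporter SLC30A6 from 77.0% to 31.1%, the zinc finger gene ZNF605 from 73.7% to 26.8%, PAOX, a polyamine oxidase, from 93.6% to 47.9%, and ATP6AP1L from 96.9% to 39.0%.

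Outside cassette exons, the largest changes without PMA lay in LSVs of 3 or more junctions. A junction rose from 13.7% to 93.8% in ARHGEF3, from 22.8% to 94.1% in SARDH, sarcosine dehydrogenase, and from 27.9% to 94.8% in the centrosomal gene CEP128. In the authors' deposited table further rises were 2.5% to 88.0% in TENM1, a teneurin, 2.6% to 73.9% in MICAL3, a monooxygenase of the MICAL family, which acts on actin, and 6.2% to 73.9% in NCAPD3, a subunit of condensin II. A junction of OXR1, a gene of oxidation resistance, fell from 86.4% to 6.8%.

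Of 16 gene lists fixed before the data were examined, actin cytoskeleton and adhesion was the 1 list whose called genes exceeded expectation past the threshold in unstimulated cells. Of its 79 measured genes 17 had a called LSV, against 4.90 expected from all genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 5.52e-05 over 32 combinations of list and state) and 7.70 expected at the same number of LSVs per gene (exact stratified test, adjusted p = 0.0143). In 3 of these genes a cassette exon rose and in 0 it fell. The exon of DIAPH1, a formin that nucleates actin filaments, rose from 37.6% to 84.0%, that of PTK2B, the focal adhesion kinase PYK2, from 50.9% to 84.2%, and that of NF2, or merlin, from 17.0% to 54.4%. Junctions rose from 20.3% to 65.5% in MYL6, a myosin light chain, and fell from 84.4% to 21.7% in EPB41, the membrane skeleton protein 4.1. The list's excess was not past the threshold without LSVs holding a de novo junction (6 genes, adjusted exact p = 0.101), with 2-junction LSVs alone (4 genes, adjusted p = 0.350) or with calls by a change of 10 points (30 genes, adjusted p = 0.245). At the same LSV number it was also lost with calls by a change of 20 points (exact stratified test, adjusted p = 0.197).

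The remaining lists were not past the threshold in unstimulated cells. In T cell receptor signalling 6 of 66 genes were called (adjusted exact p = 0.530), among them FYN, a Src-family kinase with a junction that rose from 24% to 80.6%, PIK3CD, a catalytic subunit of phosphoinositide 3-kinase with a junction that rose from 9.8% to 74.3%, and MALT1, a paracaspase. MAPK and small GTPase signalling had 7 of 77 (adjusted exact p = 0.530), including NF1, a Ras GTPase-activating protein with a junction that rose from 49.5% to 86.2%. NF-kappaB and TNF receptor signalling had 4 of 38 (adjusted exact p = 0.530), with IKBKB, a kinase of the inhibitor of NF-kappaB, falling from 96.8% to 44.4% at 1 junction, and IRAK4, a kinase downstream of Toll-like receptors, with a retained intron rising from 14.5% to 58.1%.

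Chromatin regulators had 10 of 104 called genes without PMA (adjusted exact p = 0.514), led by MTA3, a component of NuRD complexes, in which a junction fell from 68.9% to 13.2%. Cell cycle and mitosis had 9 of 108 (adjusted exact p = 0.530), with a junction of CHEK1, a checkpoint kinase, falling from 71.3% to 16.4%, one of CDK6 rising from 18.8% to 61.4%, and the exon of NUMA1, a spindle protein, rising from 46.7% to 74.5%. The ubiquitin pathway had 8 of 123 (adjusted exact p = 0.907), with junctions of the ubiquitin ligase RNF170 falling from 95.3% to 51.9% and of the deubiquitinase USP8 rising from 52.9% to 92.0%. RNA-binding proteins had 6 of 81 (adjusted exact p = 0.788) and lymphoid transcription factors 6 of 77 (adjusted p = 0.638), where a junction of MEF2A fell from 94.4% to 33.2% and the exon of ATF2 rose from 59.1% to 85.2%. Vesicle trafficking had 5 of 87 (adjusted exact p = 1), apoptosis 3 of 58 (adjusted p = 1), RNA turnover 2 of 58 (adjusted p = 0.747), core spliceosome 1 of 57 (adjusted p = 0.530) and cleavage and polyadenylation 0 of 30 (adjusted p = 0.530; 1.86 expected). In the apoptosis list a junction of CARD8 fell from 42.8% to 6.4% and in RNA turnover a junction of UPF2, a factor of nonsense-mediated decay, fell from 40.2% to 7.3%. Of 2 measured genes of other lineages 1 was called, NCAM1 (adjusted exact p = 0.481), whose exon rose from 9.8% to 51.1%.

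The second comparison asked the same of PMA-treated cells. The ARHGEF11 exon fell from 94.2% in control to 4.8% in depleted cells, and the exon of PPFIA1, liprin alpha 1, at positions 70197100 to 70197129 of chromosome 11, from 96.0% to 11.7% in the authors' deposited table of PMA-treated cells. FAM188A, a deubiquitinase gene, rose from 2.7% to 76.5%. In BIN1, whose protein bends membranes, inclusion fell from 93.4% to 17.0% at an exon whose far end was not read. In all, 1713 LSVs (1.87%) in 1165 genes (10.6%) were called.

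Of 20153 cassette exons measured with PMA, 235 were called, 100 with higher and 135 with lower inclusion (42.6% higher, two-sided exact binomial test, p = 0.0263). This excess of lower exons was not past the threshold at a posterior probability of 0.99 (49.0% higher, exact p = 0.873), without de novo LSVs (43.1%, p = 0.0623) or from source LSVs alone (45.5%, p = 0.338). Large rises in the authors' deposited table included the zinc finger gene ZNF248, from 19.5% to 93.1%, and PPP1R12A, the targeting subunit of myosin phosphatase, from 8.4% to 70.1%. As means of source and target LSVs, UGGT1, a folding sensor of the endoplasmic reticulum, rose from 20.4% to 83.8%, and APBB2, which binds the amyloid precursor protein, from 18.2% to 81.2%. The exon of FAT1, an atypical cadherin, rose from 11.9% to 73.3%, and an exon of LRCH4 from 15.8% to 86.5%. Large falls included GOLGA2, a matrix protein of the Golgi, whose exon at positions 131029473 to 131029553 of chromosome 9 went from 65.5% to 11.8%, HHAT, the hedgehog acyltransferase, from 93.0% to 37.3%, ZDBF2 from 57.9% to 10.5%, AC005154.6 from 78.1% to 21.8%, and the pseudogene DDX12P, uncertain through shared reads, from 63.1% to 2.6%.

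Among other LSVs with PMA, a junction of NOXO1, an organizer of NADPH oxidase, fell from 97.1% to 6.9%, and a junction of TMEM99 fell from 97.5% to 7.5%. LIMS1, an adaptor of integrin signalling, fell from 92.2% to 14.5% at 1 junction and MCTP1 from 90.5% to 13%. In the authors' deposited table junctions rose from 2.6% to 87.9% in RGS3, a regulator of G protein signalling, from 12.7% to 96.4% in ARHGEF3, and from 6.2% to 84.7% in EML6. A junction of AC005262.2 fell from 87.5% to 5.7%.

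With PMA 3 lists exceeded expectation past the threshold. Actin cytoskeleton and adhesion had 25 called genes of 81, against 8.55 expected (Fisher's exact test, adjusted p = 7.36e-06) and 13.03 at the same LSV number (adjusted p = 0.00880, not past the threshold with calls at a posterior probability of 0.90, adjusted p = 0.0761, or by size at 20 or 10 points, adjusted p = 0.231 and 0.935). Its cassette exons rose in 6 genes and fell in 3. DIAPH1 rose from 37.6% to 80.6%, PTK2B from 38.3% to 85.3% and NF2 from 28.5% to 64.9%, while ADD3, or gamma adducin, fell from 85.7% to 39.0%. Junctions rose in MYL6 from 12.4% to 75.9%, in SSH2, a phosphatase of cofilin, from 26.8% to 82.2%, and in DST, or dystonin, from 20.5% to 72.4%, and fell in EPB41 from 97.5% to 43.3%.

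RNA-binding proteins were the second list, with 22 called genes of 82 against 8.65 expected (Fisher's exact test, adjusted p = 0.000217). At the same LSV number 13.2 were expected and the excess was not past the threshold (exact stratified test, adjusted p = 0.0999). Its cassette exons fell in 4 genes and rose in 2, CELF2 among the latter. MATR3, or matrin 3, fell from 54.2% to 12.7%, ACIN1 from 76.9% to 36.6% and HNRNPL from 77.5% to 41.0%. In the authors' deposited table a junction of MBNL1 fell from 92.6% to 44.6%, and a junction of LUC7L, a relative of a component of the U1 particle, fell from 72.6% to 21.3%. A retained intron of TIA1, an RNA-binding protein of stress granules, fell from 84.6% to 41.1% in the LSV with the largest change. Averaged over its LSVs, the TIA1 intron at positions 70455595 to 70456029 of chromosome 2 fell from 73.5% to 41.8%. The excess was also not past the threshold with 2-junction LSVs alone (9 genes, adjusted exact p = 0.0917).

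The third list held 26 measured genes with splicing events reported for CELF2, RBFOX proteins or activated JSL1 and Jurkat cells, and thus drew on earlier work in the same cells. With PMA 15 were called against 2.74 expected (Fisher's exact test, adjusted p = 1.65e-07) and 4.04 at the same LSV number (adjusted p = 2.14e-05). Without PMA 5 were called against 1.61 expected, not past the threshold (adjusted exact p = 0.128) except without de novo LSVs (5 genes, adjusted p = 0.00507) and by size at 10 points (14 genes, adjusted p = 0.0312). MAP2K7, a kinase that activates JNK, rose from 30.7% to 78.5% with PMA and from 47.0% to 81.8% without. MALT1, whose exon of 33 nucleotides lies at positions 56378153 to 56378185 of chromosome 18, rose from 42.2% to 91.2% with PMA and from 37.4% to 69.5% without. SEC16A, a scaffold of endoplasmic reticulum exit sites, rose from 11.1% to 65.4% with PMA and stood at 43.2% and 54.6% without. CLSTN1, or calsyntenin 1, rose from 2.5% to 44.7% with PMA and to 32.3% from the same control level without. A junction of FYN rose from 14% to 75.2% with PMA, one of TRAF3, an adaptor of TNF receptors, from 60.8% to 94.6%, and one of PPP3CB, a catalytic subunit of calcineurin, fell from 97.2% to 59.4%. HNRNPC, CELF1, TIAL1 and CD47 were called with PMA, and MBNL1 in both states at different LSVs. Among the genes not called in either state the highest posterior probabilities in the authors' deposited tables were 0.917 in IKZF1, 0.874 in CLK1, 0.750 in MBNL2, 0.542 in LEF1 and 0.489 in PTPRC, and MAP3K7, GATA3, RBFOX2, U2AF2, CD6 and CTCF were lower.

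The 13 other lists were not past the threshold with PMA. MAPK and small GTPase signalling had 13 of 78 (adjusted exact p = 0.424), with a cassette exon of ARHGAP12 rising from 27.5% to 72.8% and junctions of NF1 rising from 10.8% to 81.6%, of ARHGEF1 from 34.1% to 83.4% and of GIT2 from 26.7% to 80.6%. T cell receptor signalling had 11 of 68 (adjusted exact p = 0.514), with the exon of NFATC1, a transcription factor activated by calcineurin, rising from 61.0% to 95.3% and a junction of DGKZ, a diacylglycerol kinase, falling from 80.3% to 22.5%. Vesicle trafficking and endocytosis had 13 of 87 (adjusted exact p = 0.530), with BIN1, GOLGA2, SEC16A, TSC2, in which a junction fell from 76.5% to 12.3%, and STX2, a syntaxin, whose exon fell from 44.5% to 14.5%. Cell cycle and mitosis had 18 of 109 (adjusted exact p = 0.307), with falls in NEK1 from 88.1% to 50.1%, CEP70 from 96.1% to 59.4% and FANCA from 45.7% to 6.5%, and a junction of CDK12 rising from 17.9% to 57.9%. Chromatin regulators had 15 of 104 (adjusted exact p = 0.530), with the histone deacetylase HDAC9 falling from 86.7% to 47.1%, the demethylase KDM4B rising from 25.2% to 56.4%, ARID1B, a SWI/SNF subunit, rising from 52.3% to 83.5%, and junctions changed in KDM6A, from 72.7% to 29%, and H2AFY, a histone variant, from 32.0% to 74.1%.

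Lymphoid transcription factors had 7 of 80 called genes with PMA (adjusted exact p = 0.849), with the exon of RUNX1 rising from 20.2% to 62.0% and a junction of MXI1, an antagonist of MYC, falling from 89.0% to 37.3%. The ubiquitin pathway had 10 of 123 (adjusted exact p = 0.638), with junctions of FBXW7, a substrate receptor of ubiquitin ligases, falling from 81.9% to 26.3% and of CUL4A from 71.9% to 31.5%. NF-kappaB and TNF receptor signalling had 3 of 39 (adjusted exact p = 0.907), with a junction of NFKB2 falling from 91.9% to 44.6%. Core spliceosome had 5 of 57 (adjusted exact p = 0.907), with a junction of SNRPA1 rising from 42.8% to 86.2% and one of SF3B3 falling from 84.5% to 48.8%. Apoptosis had 3 of 60 (adjusted exact p = 0.530), with a junction of CASP10 rising from 28.7% to 68.6%. RNA turnover had 3 of 58 (adjusted exact p = 0.530), with junctions of TNRC6B falling from 69.1% to 20.4% and of UPF3A from 55.9% to 16.9%. Cleavage and polyadenylation had 1 of 30, CPSF4 (adjusted exact p = 0.530), and genes of other lineages 1 of 4, NCAM1 (adjusted p = 0.530), whose exon rose from 10.4% to 45.0%.

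**Figure D1:**
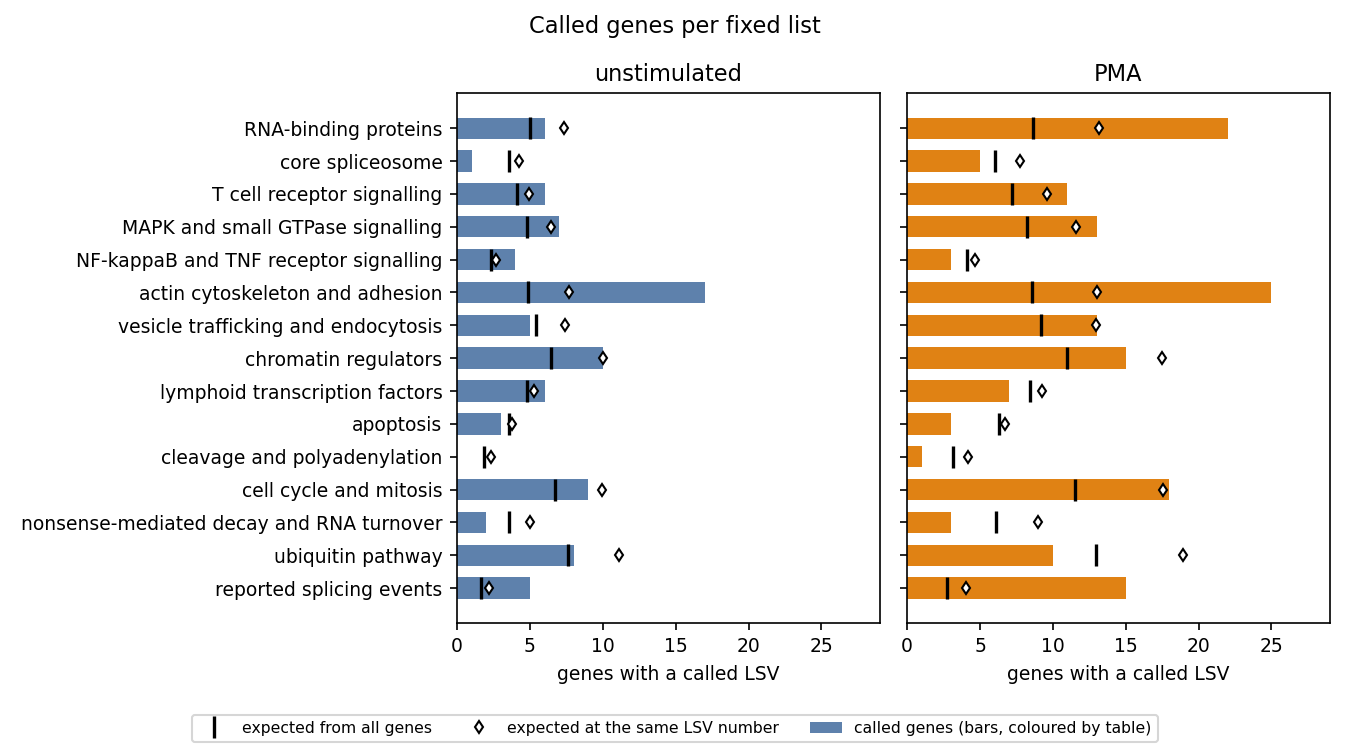
Number of genes with a called LSV (horizontal axis) in 15 of the 16 fixed lists, in unstimulated (left) and PMA-treated cells (right); bars give the genes called, vertical ticks the number expected from all genes and diamonds the number expected at the same number of LSVs per gene. The actin list has 17 and 25 called genes against 4.90 and 8.55 expected, and the list of reported splicing events 5 and 15 against 1.61 and 2.74.

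Exon skipping, as in ARHGEF11, MFSD8 and PPFIA1, was present in 78.1% of called against 71.6% of other LSVs without PMA (odds ratio 1.41, Fisher's exact test, adjusted p = 2.24e-05 over 10 tests) and in 78.9% against 71.2% with PMA (odds ratio 1.51, adjusted p = 5.65e-12). Retained introns, as in NOXO1, TIA1 and CELF2, were present in 39.1% of called against 29.6% of other LSVs without PMA (odds ratio 1.52, adjusted exact p = 6.92e-09) and in 41.3% against 29.9% with PMA (odds ratio 1.65, adjusted p = 6.23e-22). Alternative 5′ splice sites had odds ratios of 1.24 (adjusted exact p = 0.00343) and 1.33 (adjusted p = 5.45e-08), and alternative 3′ splice sites 1.06 (adjusted p = 0.455) and 1.19 (adjusted p = 0.00106). LSVs with a de novo junction did not differ past the threshold (1.06 and 1.10, adjusted exact p = 0.455 and 0.108). The largest share was at most 90% in either group in 26768 of the 91480 LSVs without PMA and 29357 of the 91729 with PMA. Against these variable LSVs, a background chosen after seeing the data, retained introns had odds ratios of 1.02 (adjusted exact p = 0.808) and 1.10 (adjusted p = 0.0645), exon skipping 1.35 and 1.45 (adjusted p = 0.000469 and 3.85e-09), and alternative 5′ and 3′ splice sites lay below 1 (0.825 and 0.909, 0.716 and 0.826). Among 2-junction LSVs alone, exon skipping also lay below 1 (0.788 and 0.832, adjusted exact p = 0.0452 and 0.0346). The tests of event types counted LSVs. The LSVs of a gene, such as the source and target LSVs of the same exon, are not independent, so these p-values can be too small.

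The third comparison asked whether depletion changed the same events in both states. In genes listed in both tables, 585 of 10517 were called without PMA and 1034 with PMA, and 258 in both, against 57.5 expected by chance (Fisher's exact test, odds ratio 9.31, p = 5.90e-113). Among them were ARHGEF11, MFSD8, FYN, MALT1, MAP2K7, DIAPH1 and GOLGA2. The actin list had 13 genes called in both states of 29 called in either, MAPK and small GTPase signalling 6 of 14, and the list of RNA-binding proteins 4 of 24. Differences between lists in this share were not tested. By LSV, 271 were called in both states against 13.6 expected. Both expectations take all genes or all LSVs as equally likely to be called. They were not adjusted for the number of LSVs per gene or for how variable an LSV is. The expected counts can therefore be too low, the odds ratio too high and the p-value too small. The junction with the largest change moved in the same direction in 267 of these 271, and in 199 of 202 genes taken once each (98.5%, exact binomial test, p = 4.27e-55). All 39 cassette exons called in both states moved in the same direction, as did 38 of 38 genes taken once each (exact binomial test, p = 7.28e-12). The 10 with the largest smaller change of the 2 states included KIF27, a kinesin, which rose from 35.0% to 88.0% without PMA and from 20.1% to 74.4% with it in the authors' deposited tables, and FMNL3, a formin, which rose from 46.0% to 86.1% and from 53.6% to 97.4%. MFSD8 rose to 67.2% from 16.6% with PMA, and MED12 fell to 58.0% from 88.6%. Across 7693 cassette exons, 1 per gene, the depletion effects in the 2 states correlated with r = 0.435, or 0.311 by rank (permutation test, p = 1e-05 for both, the smallest that 100000 permutations can give). Exons are not independent replicates.

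**Figure D2:**
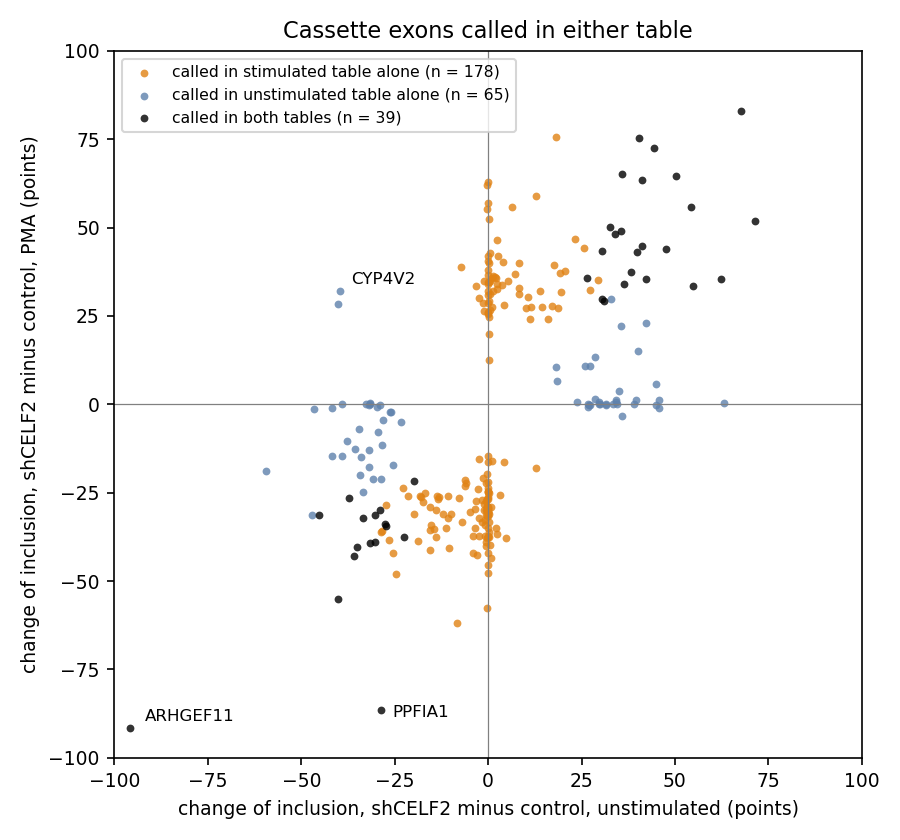
Change of inclusion after CELF2 depletion in percentage points, in unstimulated (horizontal axis) and PMA-treated cells (vertical axis) for the 282 cassette exons called in either state and measured in both. Changes are the authors' estimates, averaged where both source and target LSVs were listed. Black points mark the 39 called in both, blue the 65 called without PMA alone and orange the 178 called with PMA alone; all 39 black points lie in the lower left or upper right part of the panel.

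Exons with the largest difference between the depletion effects of the 2 states were examined next. Of 282 exons called in either state and measured in both, 184 had depletion effects at least 20 points apart, 79 more positive and 105 more negative with PMA. This count does not measure how often effects differ between states, since most of these exons were chosen by a call in 1 state alone and the authors' model shrinks changes that are not called. The exon of SLMAP, a membrane-associated protein, was at 88.7% in control and 84.1% in depleted cells without PMA, and rose from 22.8% to 83.3% with PMA. These are means of source and target LSVs in the authors' deposited tables. FAT1 was at 69.6% and 71.7% without PMA, and rose with PMA as given above. PPFIA1 fell from 97.1% to 69.2% without PMA, a smaller change than the one with PMA. CYP4V2, a cytochrome P450, fell from 44.6% to 5.9% without PMA and was at 51.9% and 83.7% with PMA, where it was not called. ZKSCAN3, a zinc finger gene, fell from 56.5% to 16.6% without PMA and was at 6.0% and 35.8% with it, also not called. ANKRD20A5P was at 67.3% and 72.7% with PMA. It was read from 2 LSVs without PMA and from 1 with PMA, so part of its difference may come from the set of LSVs. No test of these differences was possible without values per library. The source and target LSVs of an exon, read from partly different junctions, gave depletion effects that differed by an SD of 2.65 points over 4451 exons without PMA and 3.22 points over 4425 with PMA, and by 16.7 points over the 29 called exons without PMA and 14.3 points over the 69 with PMA. These effects are the authors' shrunken estimates. Over all exons their median absolute difference was 0.00103 points without and 0.00222 with PMA, so the SD over all exons understates the spread of the shares.

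**Figure D3:**
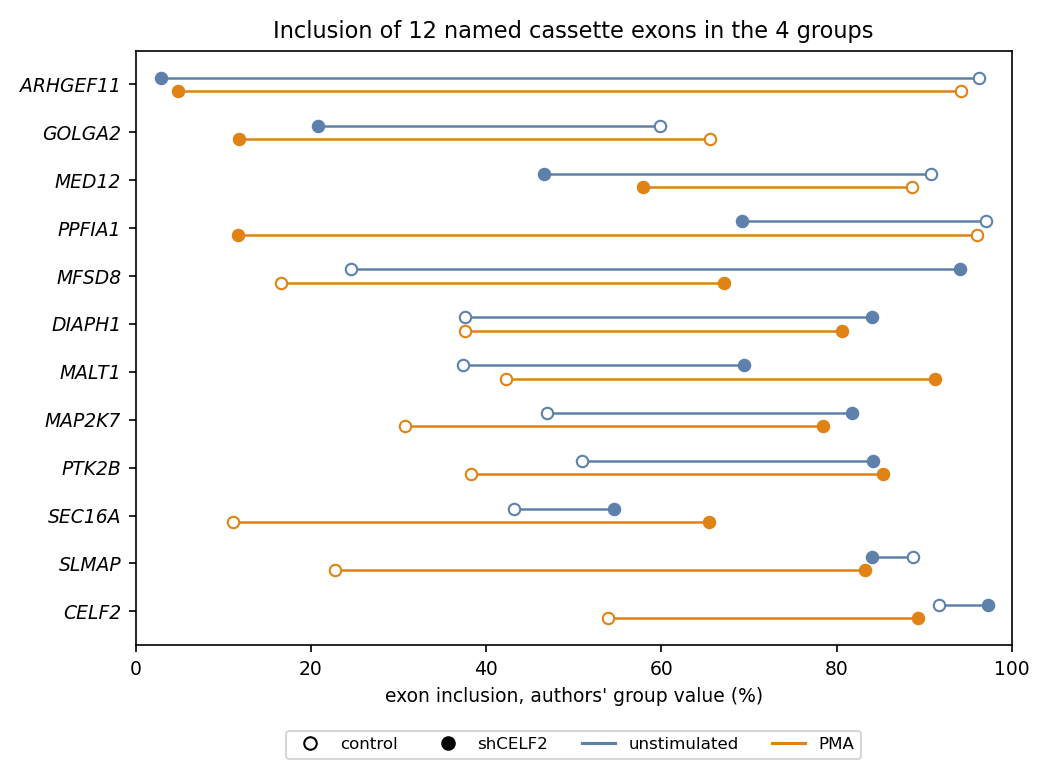
Inclusion of 12 named cassette exons as the authors' group values in percent (horizontal axis), averaged where both source and target LSVs were listed. Open circles mark control and filled circles depleted cells, joined by blue lines without PMA and orange lines with PMA. ARHGEF11 falls from 96.3% to 2.9% and from 94.2% to 4.8%, while SLMAP and CELF2 differ between control and depleted cells mainly with PMA.

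The fourth comparison set PMA-treated against unstimulated cells. Values came from tables that the authors quantified separately, so no exon was tested singly. In control cells FBRSL1 stood at 91.3% without and 39.8% with PMA, and in depleted cells at 69.4% and 25.4%. GK5, a glycerol kinase gene, stood at 26.7% and 56.7% in control cells and at 15.8% and 55.1% in depleted cells, and DDX26B at 80.9% and 39.8% in control and 64.5% and 34.0% in depleted cells. TTI2 had 51.6% and 27.6% in control and 64.1% and 10.5% in depleted cells, and B3GALNT2, a glycosyltransferase, 44.6% and 91.3% in control and 29.9% and 50.4% in depleted cells. Both exons were read from 1 LSV in 1 state and from 2 in the other, so part of their difference may come from the set of LSVs. The counts and correlations of PMA effects include such exons. CRHR1-IT1 had 7.3% and 80.4% in control cells, against 52.0% and 70.8% in depleted cells. ENSG00000163486 had 38.0% and 83.0% in control and 21.7% and 59.8% in depleted cells, and CYP4V2, given above, completes the 8 exons with the largest mean difference. Of 19201 cassette exons measured in both states, 292 differed by at least 20 points between states in control cells, 178 higher and 114 lower with PMA, and 175 in depleted cells, 87 higher and 88 lower. Of these, 35 differed in the same direction in both kinds of cells and 3 in opposite directions. Across 7693 exons the PMA effects in depleted and control cells correlated with r = 0.242, or 0.172 by rank (permutation test, p = 1e-05 for both, the smallest possible).

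The direction of PMA against that of depletion was compared by the mean effect of each over the 4 groups, which share no error if all groups are equally precise. Across 7693 exons they correlated negatively, with r = -0.192, or -0.0808 by rank (permutation test, p = 1e-05 for both, the smallest possible). SEC16A stood at 43.2% and 11.1% without and with PMA in control cells, and at 54.6% and 65.4% in depleted cells. PPP1R12A stood at 39.2% and 8.4% in control and at 79.5% and 70.1% in depleted cells, and ZNF248 at 55.2% and 19.5% in control and at 94.5% and 93.1% in depleted cells. In HNRNPL control cells had 53.1% without and 77.5% with PMA, and depleted cells 41.5% and 41.0%. Each of these exons had its larger depletion effect with PMA. The PMA-treated control value sets both that effect and the PMA effect in control cells, so opposition is partly built into these examples. In depleted cells PMA moved SEC16A by 10.8 points, the direction of depletion, PPP1R12A by -9.4, ZNF248 by -1.4 and HNRNPL by -0.5. Other named exons did not follow the negative correlation: MALT1, NF2 and FMNL3, whose inclusion rose after depletion, had positive mean effects of PMA (13.3, 11 and 9.45 points), and PPFIA1, which fell after depletion, had a negative one (-29.3 points). PMA moved PPFIA1 by -1.1 points in control and -57.5 in depleted cells. MALT1 and FMNL3 also moved more in depleted cells, while NF2 moved by 11.5 points in control and 10.5 in depleted cells. The PMA-treated depleted value sets both the PMA effect in depleted cells and the depletion effect with PMA. A shared direction is therefore partly built into PPFIA1, MALT1 and FMNL3.

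Exon length was taken from the exon bounds in the tables. With PMA, exons that fell after depletion, such as those of GOLGA2 and PPFIA1, had a length divisible by 3 in 51.9% of 133 exons, against 36.3% of exons not called (odds ratio 1.89, Fisher's exact test, p = 0.000274), a difference not past the threshold from target LSVs alone (odds ratio 1.52, p = 0.0776). The share was 43.0% of 100 exons that rose with PMA (exact p = 0.176), 44.9% of 69 that rose without PMA (p = 0.169) and 44.8% of 58 that fell without PMA (p = 0.220). A background of variable exons was not run for frame or length. A trait of variable exons in general therefore cannot be told apart from one of exons that fell after depletion. Called exons had a median length of 134 nucleotides against 122 without PMA (permutation test, p = 0.138) and 138 against 122 with PMA (permutation test, p = 0.00968). The bounds can include retained intron, as in APBB2 and SLMAP. In addition, 1331 of 19822 exons without PMA and 1315 of 19713 with PMA are listed with 11 nucleotides, a placeholder where 1 end of the exon was not read. The named exons of BIN1, DZIP1, RUNX1 and CYP4V2 are among them. Without the exons listed with 11 nucleotides, a choice made after seeing the data, the odds ratio for exons that fell with PMA was 1.78 (Fisher's exact test, p = 0.00113). The medians with PMA were then 141.5 nucleotides in called against 128 in other exons (permutation test, p = 0.0320). In exons with both junctions read, with lengths taken from those junctions, a choice made after seeing the data, called exons were shorter by the median (-20.0 nucleotides, permutation p = 0.153, and -14.0, p = 0.125).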

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

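The alternatives with 1 LSV per set of overlapping genes, a background of variable LSVs, exon lengths from junctions and leaving out exons listed with 11 nucleotides were chosen after seeing the data; the others were planned. Over the main results, 96 comparisons with an alternative kept their direction and side of the threshold or stayed within 1.5 times, 18 counts moved further, 6 results were no longer past the threshold, 5 came past it and 7 turned direction. For single lists and event types the numbers were 456 kept, 15 no longer past, 26 newly past and 81 turned. The overlap of called genes, the shared direction of LSVs called in both states and the 3 correlations across exons kept their sign and stayed past the threshold under each alternative run for them. The shared direction ranged from 89.5% to 100%, the correlation of depletion effects from 0.423 to 0.489, that of PMA effects from 0.217 to 0.271 and that of PMA against depletion from -0.210 to -0.160. The correlation of depletion effects used the authors' shrunken changes and the others used differences of group values, so their sizes are not comparable. No paired analysis was possible because the authors' tables hold 1 pooled value per group, which also ruled out leaving out single replicates. The motif alternatives were not run, since no hg19 sequence was used here. Depth per LSV is unknown, so its part in the calls could not be measured. Except where fewer LSVs or a lower bar for calls sets a count, the cause was not tested.

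At a posterior probability of 0.99, 554 LSVs were called without PMA and 1082 with PMA, and the share of called cassette exons with higher inclusion with PMA was 49.0% (exact p = 0.873). By a change of 20 points alone 2194 and 3518 were called, and 5 list results were past the threshold at the same LSV number against 3 of the 32 combinations in the report. With PMA reported events (18 genes) and RNA-binding proteins (39) were in excess and the core spliceosome (6) and the ubiquitin pathway (20) fewer than expected, and without PMA the core spliceosome (2) was fewer, while the actin list was not past the threshold. By a change of 10 points 5755 and 8555 were called and 10 list results were past the threshold from all genes, against 4 in the report. All 10 were in excess: reported events, RNA-binding proteins, chromatin regulators and cell cycle in both states, and the actin list and vesicle trafficking with PMA. At 10 points the share of higher cassette exons without PMA was 47.6% (exact p = 0.207, turned), and 1088 exons in control and 978 in depleted cells differed by that much between states. At 10 points the odds ratio for lengths divisible by 3 was 1.55 for exons that rose and 1.31 for exons that fell without PMA, and 1.53 for exons that rose with PMA, all newly past the threshold. The median length difference of called exons was then 8 nucleotides without PMA (newly past) and 4 with PMA (no longer past).

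Without LSVs holding a de novo junction 287 and 529 LSVs were called, and 43.1% of called cassette exons with PMA were higher (exact p = 0.0623). In that setting 2 event types were past the threshold, retained introns gave no value, and odds ratios lay below 1 for alternative 3′ splice sites, 0.872 without and 0.914 with PMA, and for alternative 5′ splice sites without PMA, 0.954. With 2-junction LSVs alone 312 and 595 LSVs were called. Odds ratios without and with PMA were then 0.495 and 0.445 for alternative 3′ sites, 0.754 and 0.677 for alternative 5′ sites, 0.745 and 0.701 for de novo junctions, and 0.788 and 0.832 for exon skipping. All of these but alternative 5′ sites without PMA were past the threshold in the direction opposite to the report. Against variable LSVs they were 0.716 and 0.826 for alternative 3′ sites, 0.825 and 0.909 for alternative 5′ sites and 0.866 and 0.841 for de novo junctions. Of these, alternative 3′ sites in both states, alternative 5′ sites without PMA and de novo junctions with PMA were past it, so the excess of these types depends on the background.

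From source LSVs alone, 46.4% of called cassette exons were higher without PMA (exact p = 0.630, turned) and 45.5% with PMA (p = 0.338). The number of exons whose depletion effects differed by 20 points was 105 from source LSVs, 111 from target LSVs and 40 from exons with both. The odds ratio for lengths divisible by 3 among exons that rose without PMA was 2.37 from source LSVs (exact p = 0.0172) and 0.924 from target LSVs (p = 0.874), and for exons that fell with PMA 1.52 from target LSVs (p = 0.0776). The median length difference with PMA was 7 nucleotides from source LSVs (permutation p = 0.338). It was -15.0 without and -4 with PMA in exons with both LSVs, and -20.0 and -14.0 with lengths from junctions, which also needs both junctions read, so the turn goes with the choice of exons and not with the source of the length alone. Without exons listed with 11 nucleotides no length or frame result changed direction or side of the threshold.

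Some lists that were not past the threshold crossed their expected count. At a posterior probability of 0.90 these were, without PMA, lymphoid transcription factors (6 genes) and vesicle trafficking (10). At 0.99 they were NF-kappaB signalling (3), lymphoid transcription factors (6) and the ubiquitin pathway (9) with PMA, and chromatin regulators (3), RNA-binding proteins (2) and vesicle trafficking (4) without. By size at 20 points they were apoptosis (13) with and vesicle trafficking (14) without PMA. By size at 10 points they were T cell receptor signalling (25), apoptosis (23), other lineages (1), lymphoid transcription factors (35), RNA turnover (26) and the ubiquitin pathway (53) with PMA, and RNA turnover (18) and vesicle trafficking (33) without. Without de novo LSVs they were NF-kappaB signalling with PMA (2), and without PMA NF-kappaB signalling (1), cell cycle (2), chromatin regulators (2), lymphoid transcription factors (1), RNA-binding proteins (1) and the ubiquitin pathway (3). With 2-junction LSVs alone they were NF-kappaB signalling with PMA (2), and without PMA chromatin regulators (2), RNA-binding proteins (1), the ubiquitin pathway (2) and vesicle trafficking (3). Against variable LSVs they were RNA-binding proteins (6) and the ubiquitin pathway (8) without PMA.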

Other observations

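The tests of narrower posteriors, of a larger depletion effect with PMA, of unequal reading error, of shared error of 1 group and of introns at large were chosen or changed after results were seen, and the bounds for introns were split by state once the shares were known. Under the bounds first written for introns, which took both states as 1 test, the outcome was undecided. The test of noisier group values was written down beforehand. The introns named in the next paragraph were chosen after their values were seen.

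Retained introns formed a large part of the called LSVs. Without PMA 213 introns were called, 137 with higher and 76 with lower retention in depleted cells, and with PMA 377, 214 higher and 163 lower, counting every intron of a gene and every gene ID. Taken once per gene, a count added after seeing the data, 109 were higher and 63 lower without PMA (two-sided exact binomial test, p = 0.000561), and 170 were higher and 150 lower with PMA, a difference not past the threshold (p = 0.288). Retention levels in this paragraph are means of the authors' deposited values over the LSVs that list an intron. FANCA, a gene of the Fanconi anaemia repair pathway, had several called introns. The one at positions 89806508 to 89807211 of chromosome 16 rose from 22.8% to 82.0% without PMA and from 36.8% to 64.7% with PMA. An intron of PRKAG1, a subunit of the AMP-activated kinase, rose from 8.3% to 64.9% without and from 5.6% to 51.0% with PMA. Introns of RECQL4, a DNA helicase, rose without PMA, 1 of them from 5.2% to 49.4%. With PMA an intron of NOXO1 rose from 2.9% to 93.1%, one of GPS2, a subunit of the NCoR complex, from 14.3% to 77.3% (15.2% to 54.8% without PMA), and one of IRF7, an interferon regulatory factor, from 12.05% to 57.2%. An intron of EXOC4, a subunit of the exocyst, fell in both states, from 53.2% to 7.0% and from 66.3% to 5.9%, and introns of KREMEN2 fell with PMA, 1 of them from 96.9% to 20.8%.

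The first pattern is the larger number of calls with PMA, 1713 against 901. Narrower posteriors in that table would raise the share called at a given difference, and at a raw difference of 20 to 30 points 546 of 2350 LSVs with PMA and 253 of 1507 without were called, a ratio of 1.38 (95% interval 1.21 to 1.58), so they may contribute and stay open; the bin of 30 to 40 points, first planned, decides nothing, since 91.6% were called there without PMA. Noisier group values, as the source of all calls with PMA alone, would give calls with no tie to the other state. LSVs called with PMA alone had the sign of the unstimulated table in 80.9% of 902 genes (95% interval 78.2% to 83.4%), against 77.7% of 408 genes for those called without PMA alone. This argues against noise as the source of all these calls, but not of a part of them. Error variance of group inclusion, as read from source and target disagreement, was 4.99 (control) and 4.28 (depleted) squared points with PMA. Without PMA it was 3.73 (control) and 3.998 (depleted), so noisier values may contribute and stay open. In genes with an LSV called in both states the absolute change was larger with PMA in 57.9% of 202 (95% interval 50.8% to 64.8%). That change is the authors' shrunken estimate, which narrower posteriors would also enlarge. A larger depletion effect with PMA therefore stays open and cannot be told apart from narrower posteriors by this share. Differences between libraries of a group stay open, since the tables pool them.

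The second pattern is the opposite direction of PMA and depletion, r = -0.192 over 7693 exons. Unequal error of the groups, as read from source and target disagreement, predicted 7.38% of the observed covariance over the 2977 exons with both readings (-0.247 of -3.34 squared points, against -6.93 over all 7693 exons). This argues against reading error as the whole cause in those exons, where r stayed negative with each effect from the other reading (-0.122 and -0.154), but leaves out differences between libraries and error in the shared skipping junction. Larger error of the PMA-treated control or the unstimulated depleted group may also be a cause. The pairs of effects that share these groups correlated with r = -0.542 (permutation test, p = 0.0001, the smallest that 10000 permutations can give) and -0.334, but a true opposition gives the same signs. The pairs that share the other groups were positive (0.137 and 0.262), a sign that error of those groups gives and a true opposition alone does not. Error of a group, or effects that differ between states, must therefore enter at least the positive pairs. For the negative pairs, error of 1 group and a biological opposition of PMA and CELF2 depletion cannot be told apart with these tables.

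The third pattern is the excess of called introns with higher retention in depleted cells. Against an even split it held once per gene only without PMA. Retention of introns at large, from RNA quality or nuclear RNA in the libraries, may account for part of it without PMA, since 55.6% of 2505 introns not called, 1 per gene with retention of 10% to 90%, were also higher in depleted cells (95% interval 53.7% to 57.6%). Called introns, once per gene, were higher in 63.4% (95% interval 55.7% to 70.6%), and the median shift of introns not called was 0.95 points, so how much of the excess a general shift explains stays open. With PMA 45.8% of 2597 introns not called were higher (95% interval 43.9% to 47.8%), a lean to lower retention. Called introns, once per gene, were higher in 53.1% in that state (95% interval 47.5% to 58.7%). An excess over an even split is not established with PMA, and a general shift to lower retention would not give one. Called introns were not tested against those not called in either state. An effect of CELF2 depletion on single introns stays open in both states.

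The ARHGEF11 exon was the 1 cassette exon that changed by at least 80 points in both states. Whether so complete a switch follows CELF2 levels or a difference between the cell populations that carry the hairpins and the controls was not tested, since each state holds 1 depleted group.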
